A study of Mus musculus with 12 samples.

How the data were processed

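RNA was measured in hepatocytes sorted by flow cytometry from perfused mouse livers, with 500000 sorted cells per library; the gate is not given in the sources used here. Per the labels' protocols, polyA RNA was made into QuantSeq 3' mRNA-Seq FWD libraries (Lexogen), which read a tag near the 3' end of each transcript. The deposited table holds raw counts of reads per gene symbol, which the authors did not scale between samples, as the values show. FastQC, cutadapt and STAR 2.6.1d and the builds mm10 and GRCm38 are named in the submitters' processing notes, without roles or order. The counter, the annotation release, any filter and any use of molecular identifiers are not given in the sources used here. Reads shared between near-identical genes (Cyp2a5 with its paralogs, Hba-a1 with Hba-a2, Ugt1a5 with the other transcripts that share the 3' end of its locus) could therefore be split by the counting, and values of those genes are uncertain.

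The table has 37141 gene rows, of which 17882 held 0 counts in all 12 libraries. Of the gene symbols, 36460 (98.17%, holding 99.39% of counts) were found in GENCODE M21, which is on the same GRCm38 build and gave the gene positions. Groups and replicate numbers came from the labels. No 2 libraries of a group agreed within sampling noise: chi-square per degree of freedom lay between 9.27 and 29.49 over all pairs. The sources used here do not state whether samples came from separate animals, so the p-values measure the spread between these samples, which may be technical.

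Counts were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 10780 genes. Libraries were scaled by TMM, 1 coefficient was fitted for each of the 4 groups over all 12 samples, and contrasts were tested by the quasi-likelihood F test with Benjamini-Hochberg adjustment at 0.05. The 5 contrasts were the injury response of each genotype, the knockout effect in each injury state, and the difference between the injury responses (the interaction). TMM factors ranged from 0.776 to 1.312. Against scaling by library totals, TMM moved the median log2 fold change: with totals it was higher by 0.37 in both injury responses, and the knockout contrasts moved by -0.14. Changes are therefore given relative to the bulk of genes.

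Sets of genes were tested with camera (limma 3.58.1) on log2 CPM with a prior count of 2, using 32 gene lists fixed before the data were examined and a preset correlation of 0.01. An estimated correlation and the fry test were run beside it. A list score is the mean log2 CPM of the tested members in a library. It was compared between groups by a two-sided exact permutation test, whose smallest p with 3 against 3 samples is 0.1. The 95% intervals of score differences pool the spread within all 4 groups and are not adjusted over lists or comparisons. Fold changes against a group with no counts were computed as lower bounds against a floor of 3 counts summed over the group, and with 1 to 3 counts as a ratio with a 95% counting interval. These counting intervals and floors cover counting error only. The alternatives tried were edgeR's RLE factors, library totals, no low-count filter, at least 5 CPM in 3 samples, DESeq2 1.42.0, limma-voom with and without sample quality weights, a replicate block, a test against a 1.5-fold change (glmTreat), fits of the 6 samples compared, and leaving out each sample in turn. Single genes were followed over all of these except limma-voom, glmTreat and the 5 CPM filter. Those enter the adjusted p ranges of Yap1 and Wwtr1 alone. A non-hepatocyte marker score as covariate (the mean of the macrophage, endothelial and stellate list scores of a library), and the 6-sample fits of single genes, were added after the data were seen.

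The genes named were chosen by a rule written before the data were examined. It took Yap1, Wwtr1, Ccn1, Ccn2, Ankrd1 and Amotl2 in every comparison. It added the 5 largest rises and the 5 largest falls among genes past the threshold with at least 20 CPM in 1 group and no overlap between replicates, leaving out predicted gene models. It also took 2 members with the smallest adjusted p, among those past the threshold, in each of the 6 lists with the smallest camera p, 2 members of each of 4 key lists (YAP/TAZ targets, S phase, G2 and mitosis, pericentral hepatocyte), and the 2 most abundant members of each marker or technical list. In the interaction the rule took the first 6 genes and any gene past the threshold. The values of 1 gene that the rule took are not reported here. For 73 pairs of a marker or technical gene and a comparison that did not pass the threshold no fold change is given; this restriction was made after the data were seen, when many such genes near 0 were found to change sign between settings.

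Recovery was tested on simulated counts with known changes. Changed genes were drawn only among genes that passed the low-count filter and a higher minimum total count. Recovery of rarer genes was therefore not measured. Of genes changed 4-fold, 45.2% were recovered in each injury response, 46.9% for the uninjured knockout, 75.4% for the injured knockout and 19.7% for the interaction. At 2-fold the shares were 0%, 3.2%, 13.6%, 9.2% and 1.5% for the control injury response, the knockout injury response, the uninjured knockout, the injured knockout and the interaction. Each gene was drawn independently of the others, so the simulations held no variation that genes share within a library. In both injury simulations all groups started from the mean and spread of the uninjured libraries. Far fewer genes were changed than the real comparisons called. The injured libraries varied less, with a biological coefficient of variation of 0.245 against 0.408. The recovery shares therefore need not hold for the real injury responses. Among 10508 unchanged genes in the simulation of the uninjured knockout, 27 were called and 8.68% had an unadjusted p under 0.05, so this comparison was anti-conservative there. In the simulation of the injured knockout 0 of 10469 unchanged genes were called and 1.94% had an unadjusted p under 0.05, so that comparison was conservative. The share was 4.76%, 4.8% and 4.93% for the control injury response, the knockout injury response and the interaction.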

Results

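The study asked whether YAP and TAZ matter for how hepatocytes regenerate after acute liver injury. The response of hepatocytes to acute liver injury, with and without these effectors of the Hippo pathway, was measured in 12 libraries from mice carrying floxed alleles of both genes. The 4 groups of 3 samples each were uninjured controls (ctrl), injured controls (ctrl + CCl4), uninjured knockouts (Yap/Taz KO) and injured knockouts (Yap/Taz KO + CCl4). Knockouts had received 5e11 genome copies of an AAV8 vector with Cre recombinase under the hepatocyte TBG promoter, with 3 weeks between vector and injury or collection. Injury was by carbon tetrachloride (CCl4), a hepatotoxin activated by cytochrome P450 enzymes in pericentral hepatocytes, at 1 ml/kg and 48 h before collection. The labels name neither a control vector nor a vehicle injection, so each effect includes any effect of its vector or injection. Total counts ranged from 1617761 (ctrl replicate 3) to 3028951 (ctrl + CCl4 replicate 2), and 11281 to 14879 genes were detected per library. The biological coefficient of variation was 0.408 over the 6 uninjured and 0.245 over the 6 injured libraries. All 12 libraries entered 1 fit with a shared estimate of the spread. The gene tests between injured groups therefore did not use their lower spread. The first principal component held 52.5% of the variance and parted injured from uninjured libraries.

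Yap1 transcript was lower in both knockout groups. In uninjured hepatocytes it averaged 15.6 ± 6.3 CPM in Yap/Taz KO against 58.0 ± 16.1 CPM in ctrl (SD, n = 3 each), with all 3 knockout libraries (9.65 to 22.2) below all 3 controls (40.3 to 71.8). After injury the means were 14.5 ± 0.313 and 56.6 ± 8.02 CPM. The log2 fold changes of Yap1 were -1.89 (SE 0.31; edgeR, Benjamini-Hochberg adjusted p = 0.102) and -1.96 (SE 0.30; edgeR adjusted p = 0.0995). Neither passed the threshold in edgeR, while DESeq2 gave adjusted p = 0.000274 and 6.91e-06. Over all alternatives the adjusted p of Yap1 ranged from 1.26e-05 to 0.877 before and from 6.92e-07 to 0.625 after injury. In edgeR Yap1 passed before injury without ctrl replicate 1 (-2.10, adjusted p = 0.0438), and after injury without ctrl replicate 1 (adjusted p = 0.0274), Yap/Taz KO replicate 1 (0.0491) or Yap/Taz KO replicate 2 (0.0426). It also passed without the low-count filter (1.26e-05 before and 6.92e-07 after injury), and after injury in the 6-sample fit (0.00278) and with the marker score as covariate (0.0245), these 2 added after the data were seen. Wwtr1, which encodes TAZ, averaged 14.7 ± 4.18 CPM in Yap/Taz KO against 38.9 ± 17.1 in ctrl (log2 fold change -1.40, SE 0.33, edgeR adjusted p = 0.235). DESeq2 gave adjusted p = 0.0389 and edgeR without the low-count filter 0.0129. The range over alternatives was 0.0129 to 0.966, the highest from limma-voom with quality weights. Wwtr1 stood at 57.6 CPM in ctrl replicate 1 against 24.2 and 34.8 in the other controls, with all 3 knockout libraries (10.1 to 18.3) lower still. Without ctrl replicate 1 its log2 fold change was -0.98 (edgeR adjusted p = 0.267). With the marker score as covariate it was -1.13 (edgeR adjusted p = 0.201). After injury Wwtr1 averaged 23.3 ± 2.97 against 33.7 ± 1.08 CPM (log2 fold change -0.53, SE 0.31, edgeR adjusted p = 0.983). Yap1 lies on chromosome 9 from 7931999 to 8004596 and Wwtr1 on chromosome 3 from 57455649 to 57575910, both on the minus strand of GRCm38. A 3' tag outside the deleted exons measures transcript abundance and does not show whether protein was lost.

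**Figure D1:**
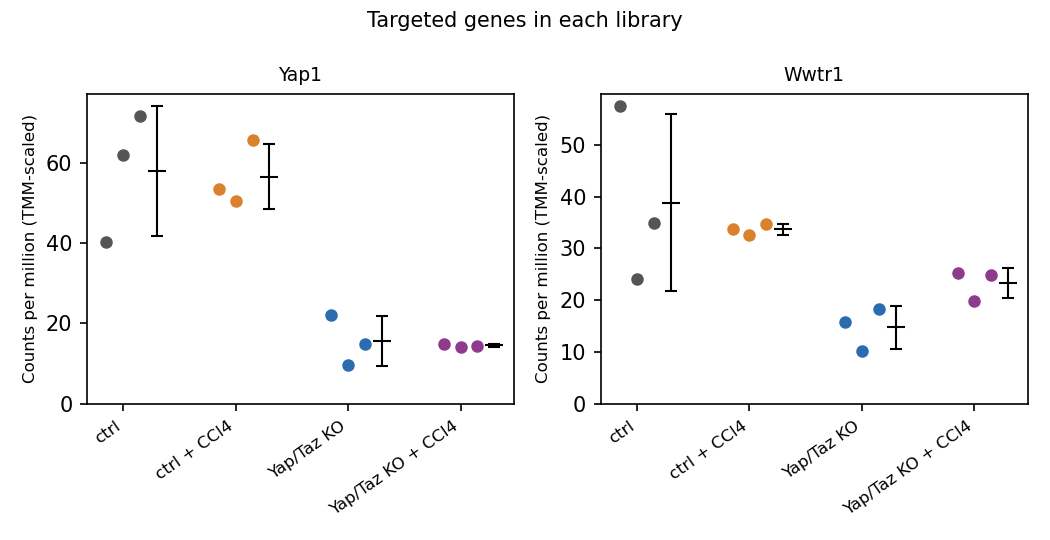
TMM-scaled CPM of Yap1 and Wwtr1 (y axes) in each library of the 4 groups (x axes); points are libraries and the bar beside them is the mean with its SD (n = 3). Yap1 lay between 9.65 and 22.2 in the uninjured knockouts and between 40.3 and 71.8 in the uninjured controls.

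In the control libraries cell division genes were higher and genes of hepatocyte function lower after injury. Markers of other cell types moved too, so which cells gave these changes is not settled. All 31 tested members of the G2 and mitosis list rose, with a median log2 fold change of 5.52 (5.38 with undetected genes at their bounds; camera adjusted p = 2.04e-31, adjusted p = 0.0484 with an estimated correlation). Cdca3, which promotes entry into mitosis, went from 0.785 ± 0.825 to 120.2 ± 9.33 CPM (SD, n = 3 each; log2 fold change 7.07, SE 0.45, edgeR adjusted p = 4.46e-07). Ube2c, which helps degrade mitotic cyclins, rose by 4.54 (SE 0.33, edgeR adjusted p = 1.08e-06). Of 33 S phase and DNA replication genes 30 rose and 1 fell (median 2.97, 2.90 with bounds; adjusted p = 0.0484 with an estimated correlation), among them Rrm1, a subunit of ribonucleotide reductase (2.97, SE 0.29), and Mcm7 of the replicative helicase (2.83, SE 0.28). Adjusted over the list alone, 31 G2 and mitosis genes rose, and 31 S phase genes rose and 1 fell.

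Metabolic lists went down. Of 21 periportal genes 18 fell (19 adjusted over the list alone; median -1.94, adjusted p = 0.0484 with an estimated correlation), including Otc of the urea cycle (-2.54, SE 0.24) and the cytochrome Cyp2f2 (-3.46, SE 0.37). Of 21 bile acid genes 16 fell (16 adjusted over the list alone; median -1.69, adjusted p = 0.0484 with an estimated correlation), including Slc27a5, which activates bile acids for conjugation (-2.71, SE 0.22), and the sterol hydroxylase Cyp27a1 (-2.83, SE 0.27). Of 18 fatty acid synthesis genes 15 fell (15 adjusted over the list alone; median -1.66, adjusted p = 0.00497 with an estimated correlation). Of 23 drug metabolism genes 20 fell (20 adjusted over the list alone; median -1.88), including Ugt2b1 (-2.06, SE 0.24) and Cyp2d22 (-2.53, SE 0.30), with adjusted p = 0.108 with an estimated correlation. The pericentral list had 11 falls and 1 rise among 21 genes (also adjusted over the list alone; median -1.26, adjusted p = 0.102 with an estimated correlation), including the glutamine synthetase gene Glul (-3.48, SE 0.31) and Cyp2e1 (-4.63, SE 0.46), whose product activates CCl4. In the cytoskeleton and injury list 15 of 22 genes rose (17 adjusted over the list alone; median 2.03, adjusted p = 0.143 with an estimated correlation), with the tubulin Tubb6 at 5.07 (SE 0.50) and galectin 3 (Lgals3) at 4.69 (SE 0.47).

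The largest falls under the naming rule were Rgs16, a regulator of G protein signalling (log2 fold change -7.67, SE 0.98), the hepcidin family gene Hamp2 (-7.16, SE 0.54), Cyp2c38 (-5.96, SE 0.44), Cyp2a5 (-5.63, SE 0.59) and the glutamate transporter gene Slc1a2 (-5.45, SE 0.57). The largest rises were in genes with few or no counts in ctrl. Akr1c18 was at least 47.3-fold higher, the spindle gene Dlgap5 at least 41.8-fold higher, the cell cycle transcription factor Foxm1 at least 41.6-fold higher and the kinesin Kif2c at least 38.8-fold higher. Kif11, a mitotic kinesin, had 1 count in ctrl and a ratio of 241 (95% counting interval 43.0 to 9540).

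In the YAP/TAZ target list 1 of 17 tested genes rose and 1 fell, also adjusted over the list alone. Myof rose by 3.50 (SE 0.52, edgeR adjusted p = 0.000248) and Igfbp3 fell by 2.02 (SE 0.61, edgeR adjusted p = 0.0273) on the log2 scale, and the list did not pass (camera adjusted p = 0.495). Ccn1 (0.16), Ccn2 (-1.96), Ankrd1 (2.22) and Amotl2 (-0.60) did not pass. Ccn2 had 232 counts in ctrl replicate 1 and 1 and 3 in the other ctrl libraries, and without that library its log2 fold change was 2.79 (edgeR adjusted p = 0.0461, range over alternatives 8.5e-05 to 0.461, the lowest without the low-count filter). Igfbp3 was lost without ctrl replicate 1 (-0.63, edgeR adjusted p = 0.38), and without ctrl + CCl4 replicate 1, 2 or 3 (edgeR adjusted p = 0.0832, 0.0864 and 0.0869, range over alternatives 0.000493 to 0.38). Yap1 (-0.03, SE 0.28) and Wwtr1 (-0.21, SE 0.31) did not pass, and both signs turned with library totals (0.37 and 0.16).

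Markers of other cell types moved with injury. The macrophage and Kupffer cell score was 5.66 ± 1.23 log2 CPM in ctrl and 7.11 ± 0.338 in ctrl + CCl4, the monocyte and neutrophil score 2.14 ± 0.966 and 4.84 ± 0.378, and the stellate cell score 4.09 ± 1.09 and 5.87 ± 0.331 (SD, n = 3). The cholangiocyte and progenitor score was 2.75 ± 0.137 and 3.89 ± 0.105 (difference 1.14, 95% interval 0.725 to 1.56, exact permutation p = 0.1), although its list did not pass. The two-sided exact permutation p of the macrophage, monocyte and stellate scores was 0.2, 0.1 and 0.1, where 0.1 is the smallest possible. Camera called these 3 lists higher, with adjusted p = 0.563, 0.172 and 0.439 with an estimated correlation. Spp1, a cholangiocyte and progenitor marker, rose by 4.10 (SE 0.46, edgeR adjusted p = 2.6e-05) and Lyz2 of macrophages by 3.23 (SE 0.59, edgeR adjusted p = 0.00124). Hbb-bs, a haemoglobin gene, fell by 2.92 (SE 0.95, edgeR adjusted p = 0.0375), with 1408 counts in ctrl replicate 1 against 19 and 66 in the other controls. Without that library it stood at 0.035 (edgeR adjusted p = 0.973, range over alternatives 8.76e-20 to 0.973), and its call was also lost without any 1 of the 6 injured libraries (edgeR adjusted p = 0.0503 to 0.141).

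In all, 2427 of 10780 genes changed in control hepatocytes, 1137 up and 1290 down, of which 1957 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Camera called 19 of the 32 lists, 8 higher and 11 lower. Also called lower were hepatocyte identity (18 of 27 fell, 19 adjusted over the list alone, median -0.98), cholesterol synthesis (18 of 24 fell, 19 adjusted over the list alone, median -0.93), circadian clock (-1.04) and female-biased genes (-2.51), each with adjusted p = 0.143 with an estimated correlation. Male-biased genes (-2.19) and fatty acid oxidation (-0.96) were lower, with adjusted p = 0.132 and 0.313 with an estimated correlation. The acute phase response (0.58) and fetal liver genes (0.95) were higher, with adjusted p = 0.337 and 0.214 with an estimated correlation. Acute phase was lost without ctrl replicate 1 (camera adjusted p = 0.153) or 2 (0.0558), and fetal liver without ctrl replicate 3 (0.105) or with library totals (0.0959). The macrophage list was lost with fry (0.115), and circadian clock with the marker score as covariate (0.2). That covariate holds the macrophage list itself, so the loss of that list with it (0.807) follows from its construction. The camera adjusted p was 0.312 for Hippo components, 0.059 for G1 and growth control, 0.278 for p53 targets, 0.932 for NRF2 targets, 0.624 for the unfolded protein response, 0.545 for interferon response and 0.893 for immediate early genes. It was 0.184 for cholangiocytes, 0.924 for endothelial cells, 0.932 for lymphocytes, 0.326 for erythroid cells and 0.924 for mitochondrially encoded genes. The medians of NRF2 targets (-0.05), the unfolded protein response (0.04), lymphocytes (-0.10) and mitochondrially encoded genes (0.18) had the sign opposite to camera's. Scaled by library totals, 1974 genes rose and 698 fell, so the balance of directions rests on the scaling. With the marker score as covariate, chosen after the data were seen, 1531 genes were called. The macrophage and stellate parts of that score rose with injury, by 1.449 and 1.774 log2 CPM. The lower count therefore does not show whether other cells gave the lost calls.

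In the knockout libraries division genes were also higher and metabolic ones lower after injury. All 31 G2 and mitosis genes rose, also adjusted over the list alone (median log2 fold change 6.40, adjusted p = 0.0399 with an estimated correlation), among them Ube2c (6.99, SE 0.42) and Cdca3 (7.24, SE 0.46; edgeR adjusted p = 3.43e-07 for both). Of 33 S phase genes 30 rose (32 adjusted over the list alone; median 3.56, 3.32 with bounds, adjusted p = 0.0399 with an estimated correlation), among them Rrm1 (2.71, SE 0.28) and the DNA ligase Lig1 (3.68, SE 0.42). The hepatocyte identity list had 19 falls among 27 genes (23 adjusted over the list alone), including Hpd of tyrosine breakdown (-2.48, SE 0.29) and the apolipoprotein gene Apoa2 (-2.06, SE 0.25), with adjusted p = 0.0958 with an estimated correlation. Periportal genes fell in 13 of 21 cases and rose in 1 (15 and 1 adjusted over the list alone), with Cyp2f2 at -3.39 (SE 0.37) and the immunoglobulin receptor gene Pigr at -2.79 (SE 0.30), and adjusted p = 0.0831 with an estimated correlation. Bile acid genes fell in 14 of 21 cases (16 adjusted over the list alone), with Slc27a5 at -2.87 (SE 0.23) and Cyp27a1 at -2.23 (SE 0.26), and adjusted p = 0.079 with an estimated correlation. Drug metabolism genes fell in 15 of 23 cases and rose in 1 (17 and 1 adjusted over the list alone), with adjusted p = 0.14 with an estimated correlation. Pericentral genes fell in 11 of 21 cases (13 and 1 rise adjusted over the list alone), with Glul at -3.68 (SE 0.31), and adjusted p = 0.0831 with an estimated correlation. Among 22 cytoskeleton genes 17 rose (20 adjusted over the list alone), with Lgals3 at 5.22 (SE 0.49) and Tubb5 at 2.43 (SE 0.28), and adjusted p = 0.0958 with an estimated correlation.

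The largest falls under the naming rule were Hamp2 (-6.79, SE 0.52), Slc1a2 (-6.75, SE 0.61), Cyp2c38 (-5.40, SE 0.42), the glucuronosyltransferase Ugt1a5 (-4.80, SE 0.68) and the sulfotransferase Sult2a3, which was higher in uninjured libraries by a ratio of 101 (95% counting interval 27.4 to 843). The largest rises were Cdca2 (at least 87.6-fold higher), the cell cycle phosphatase Cdkn3 (at least 63.7-fold higher), the condensin subunit Ncapg (at least 61.5-fold higher), Lockd (at least 48.7-fold higher) and the kinetochore gene Cenph (at least 47.6-fold higher), all without counts in Yap/Taz KO. The YAP/TAZ targets Myof (2.96, SE 0.53, edgeR adjusted p = 0.00137) and Axl (1.97, SE 0.57, edgeR adjusted p = 0.0266) rose among 17, and the list did not pass (camera adjusted p = 0.539). Ccn1 (0.51), Ccn2 (1.61), Ankrd1 (-0.63), Amotl2 (-0.41), Yap1 (-0.10, and 0.27 with library totals) and Wwtr1 (0.66) did not pass; without the low-count filter Ccn2 did (edgeR adjusted p = 0.00778, range over alternatives 0.00778 to 0.722).

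Marker scores moved here as well, with macrophages at 4.89 ± 1.04 and 6.85 ± 0.282 log2 CPM before and after injury and stellate cells at 3.88 ± 0.509 and 5.90 ± 0.088 (adjusted p = 0.37 and 0.301 with an estimated correlation). The monocyte and neutrophil score was 1.30 ± 0.472 and 4.15 ± 0.289 (difference 2.85, 95% interval 1.74 to 3.96, adjusted p = 0.14 with an estimated correlation). The cholangiocyte and progenitor score was 2.845 ± 0.227 and 3.415 ± 0.342 with overlap (difference 0.57, 0.151 to 0.989, exact permutation p = 0.2), and its list did not pass (camera adjusted p = 0.523). Spp1 (2.67, SE 0.44), Lyz2 (2.88, SE 0.58), Plac8 of monocytes (4.26, SE 0.55) and Sparc of stellate cells (1.87, SE 0.58) rose. With the marker score as covariate Axl stood at 0.36 (edgeR adjusted p = 0.629, range over alternatives 4.15e-09 to 0.629), Sparc, whose list is part of that score, at 0.23 (0.782, range 1.65e-10 to 0.782) and Myof at 1.48 (0.0828, range 1.34e-14 to 0.0828). Axl was also lost without Yap/Taz KO replicate 2 or 3 or Yap/Taz KO + CCl4 replicate 1 or 2 (edgeR adjusted p up to 0.097), and Sparc without Yap/Taz KO replicate 1 or 2, any 1 Yap/Taz KO + CCl4 library, or ctrl + CCl4 replicate 1 or 3 (up to 0.126).

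In all, 1916 genes changed in knockout hepatocytes, 1016 up and 900 down, of which 1509 changed at least 2-fold (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted). Camera called 18 lists, 8 higher and 10 lower, and fatty acid synthesis (12 of 18 fell, 13 adjusted over the list alone) had adjusted p = 0.00662 with an estimated correlation. The remaining 7 called lists were cholesterol synthesis, fatty acid oxidation, circadian clock and female-biased genes (lower), and acute phase, fetal liver and monocyte genes (higher), with adjusted p = 0.218, 0.261, 0.0831, 0.155, 0.177, 0.13 and 0.14 with an estimated correlation. With library totals 1814 genes rose and 406 fell, and with the marker score as covariate 643 were called. The macrophage and stellate parts of that covariate themselves rose with injury, by 1.965 and 2.019 log2 CPM, so it also takes up injury response. Calls lost with it, among them Axl, Sparc and Myof, therefore do not show whether other cells gave those changes. That covariate also ended the calls of the fatty acid oxidation (adjusted p = 0.124), circadian clock (0.158) and macrophage lists (0.419), the last of which is part of it by construction. Without Yap/Taz KO + CCl4 replicate 1 the count was 1176 and without Yap/Taz KO replicate 2 it was 1190.

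Most genes called after injury in 1 genotype moved in the same direction in the other. Across 10780 genes their log2 fold changes correlated with r = 0.777 and rho = 0.66, although genes are not independent replicates. Over all genes 71.9% had the same sign in both. Of the genes called in controls 2319 (95.55%) had the same sign in knockouts. The 95% interval of 94.65 to 96.34 takes genes as independent and so does not measure the spread between samples. Called in both were 1338 genes: 673 higher, 664 lower and 1 opposite, where independent lists would share 107.2 and 107.7. No gene passed the test of the difference between the responses (edgeR, Benjamini-Hochberg adjusted; lowest adjusted p = 0.49, Notum, an inhibitor of Wnt signalling named for that p alone). In simulated data this test recovered 1.5% of 2-fold and 19.7% of 4-fold changes, so differences of that size are not ruled out. At an unadjusted p under 0.05 there were 874 genes (8.11%), against 4.93% of unchanged genes in the simulation of the interaction. That simulation held no variation shared between genes, so these shares are not directly comparable. DESeq2 called 11 genes, limma-voom 0 and edgeR without the low-count filter 115. The list score for G2 and mitosis rose by 5.31 in controls and 5.12 in knockouts, a difference of -0.19 (95% interval -1.47 to 1.09; the median of member fold changes was 0.35, opposite in sign), and S phase by 2.82 and 2.92, a difference of 0.10 (-0.77 to 0.96). Camera called periportal (adjusted p = 0.0136), drug metabolism (0.0136) and interferon (0.0111) lists higher in the difference. With an estimated correlation the adjusted p was 0.938 for each, with fry it was 0.753 to 0.782, and adjusted over the list alone 1 drug metabolism gene and 0 periportal or interferon genes passed. Periportal and drug metabolism lost the call without ctrl replicate 3 (0.209 and 0.324), Yap/Taz KO replicate 3 (0.0549 and 0.0706) or Yap/Taz KO + CCl4 replicate 3 (0.0919 for both), and interferon without Yap/Taz KO replicate 2 (0.244) or Yap/Taz KO + CCl4 replicate 1 (0.0648). Ccn2 turned to -1.18 without ctrl replicate 1, and passed without the low-count filter (edgeR adjusted p = 1.03e-05, range over alternatives 1.03e-05 to 0.923). Yap1 (-0.07), Wwtr1 (0.87), Ccn1 (0.35), Ccn2 (3.57), Ankrd1 (-2.85) and Amotl2 (0.20) did not pass.

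**Figure D2:**
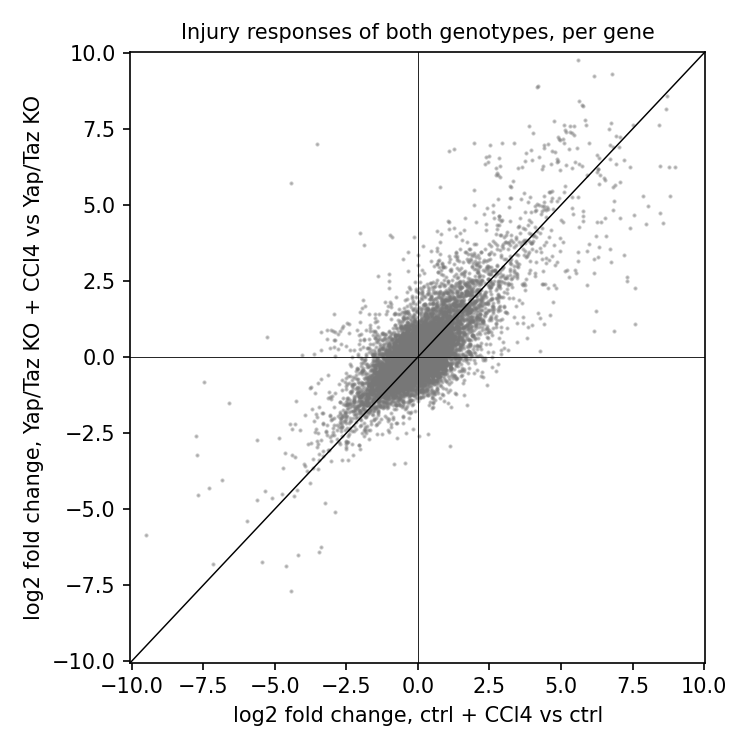
Log2 fold changes after injury in controls (x axis) and knockouts (y axis), 1 point per gene for 10780 genes; the diagonal marks equal responses. Pearson's r across genes was 0.777.

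Before injury the transcriptomes of knockouts and controls were compared for effects of the knockout alone, and no gene differed between them in edgeR (0 of 10780, Benjamini-Hochberg adjusted; lowest adjusted p = 0.102, Efna1, named for that p alone). At an unadjusted p under 0.05 there were 1020 genes (9.46%), against 8.68% of unchanged genes in the simulation of this comparison. Simulated genes varied independently, so these shares are not directly comparable. DESeq2 called 39 genes, limma-voom 0 and edgeR without the low-count filter 210. The YAP/TAZ target Ccn1 lay between 2.13 and 9.75 CPM in Yap/Taz KO and between 12.3 and 24.2 in ctrl (log2 fold change -1.63, SE 0.61, edgeR adjusted p = 0.449). Ccn2 stood at -2.98 (SE 1.20, edgeR adjusted p = 0.476) and at 1.77 without ctrl replicate 1. Ankrd1 (1.29) and Amotl2 (-0.26) did not pass, and neither did the target list (median -0.30, camera adjusted p = 0.367). The mitosis genes Ube2c (-2.84, SE 0.53) and Cdca8 (-2.83, SE 0.60) and the replicative helicase genes Mcm5 (-2.70, SE 0.83) and Mcm6 (-1.63, SE 0.76) did not pass, with means in ctrl of 4.72, 4.98, 6.51 and 8.41 CPM. The pericentral genes Tcf7 (1.35, SE 0.69) and Gulo (0.34, SE 0.21) did not pass either. Mcm5 passed without ctrl replicate 2 (edgeR adjusted p = 0.0143, range over alternatives 0.000556 to 0.705), and Mcm6 turned to 0.30 without ctrl replicate 1. Without the low-count filter edgeR called Ube2c (adjusted p = 0.000673, range over alternatives 0.000673 to 0.554), Cdca8 (0.00147, range 0.00147 to 0.604), Mcm5 (0.000556), Mcm6 (0.0186, range 0.0186 to 0.908) and Ccn2 (2.53e-07, range 2.53e-07 to 0.913).

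Among lists, camera called 2 higher and 4 lower before injury. Pericentral (median 0.22, camera adjusted p = 0.0228) and hepatocyte identity genes (0.16, camera adjusted p = 0.00585) were higher. Interferon (-0.50, camera adjusted p = 0.00154), macrophage (-0.87, 0.00154), monocyte (-2.29, 0.0228) and erythroid genes (-3.91, 0.0228) were lower. The adjusted p with an estimated correlation was 0.841 for each, and with fry 0.588 to 0.783. Pericentral, identity and monocyte calls were lost with the marker score as covariate (0.211 for each), and monocyte and erythroid calls with library totals (0.056 and 0.055). Adjusted over the list alone 2 monocyte and 4 erythroid genes were lower, and 0 in the other 4 lists. The erythroid score was 8.54 log2 CPM in ctrl replicate 1 against 2.31 and 5.24 in the other controls, and without that library 0 lists were called, with medians of 0.069 for pericentral, 0.053 for identity, -0.303 for interferon, 0.187 for macrophage, -0.031 for monocyte and -1.08 for erythroid genes. The pericentral call was also lost without Yap/Taz KO replicate 1 (0.136). Without Yap/Taz KO replicate 2 the count was also 0, with medians of 0.231, 0.068, -0.217, -0.575, -1.83 and -3.475 in the same order. It was 11 without ctrl replicate 2, 12 without ctrl replicate 3 and 15 without Yap/Taz KO replicate 3.

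After injury no gene differed between knockouts and controls in edgeR (0 of 10780, Benjamini-Hochberg adjusted; lowest adjusted p = 0.0995, Yap1). At an unadjusted p under 0.05 there were 613 genes (5.69%), against 1.94% of unchanged genes in the simulation of this comparison. As simulated genes varied independently, the excess over that share does not show a knockout effect. DESeq2 called 18 genes, limma-voom with quality weights 17, limma-voom 0 and edgeR without the low-count filter 109. Cyp2a5, a pericentral cytochrome P450, averaged 65.7 ± 45.3 CPM in Yap/Taz KO + CCl4 and 6.28 ± 4.09 in ctrl + CCl4 (log2 fold change 3.40, SE 0.55, edgeR adjusted p = 0.102, DESeq2 adjusted p = 7.71e-08, range over alternatives 3.76e-24 to 1), and passed in edgeR without Yap/Taz KO + CCl4 replicate 1 (adjusted p = 0.00575), without the low-count filter (3.76e-24), in the 6-sample fit (0.0424) and with the marker score as covariate (0.0245). Gulo of vitamin C synthesis stood at 0.87 (SE 0.21; DESeq2 adjusted p = 0.0219, range over alternatives 0.0219 to 1), the cytokinesis gene Kif23 at -0.95 (SE 0.37), Cenpf at -0.86 (SE 0.41) and Mcm10 at 0.76 (SE 0.35). The YAP/TAZ targets Myof (-0.94, SE 0.44), Ccn1 (-1.27, SE 0.56), Ccn2 (0.59, SE 1.08), Ankrd1 (-1.56, SE 0.85) and Amotl2 (-0.06, SE 0.35) did not pass, nor did the list (median -0.29, camera adjusted p = 0.108).

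Lists moved apart after injury by camera. Higher in the knockouts were drug metabolism (23 of 23 members positive, median 0.54, adjusted p = 8.44e-07), periportal (0.50, 1.59e-06), cholesterol synthesis (0.39, 1.59e-06), bile acid (0.26, 7.84e-06), pericentral (0.39, 1.82e-05), hepatocyte identity (0.35, 0.000126), fatty acid synthesis (0.30, 0.00843) and female-biased genes (0.65, 0.0222). Lower were G2 and mitosis (31 of 31 members negative, -0.39, 3.42e-05), cytoskeleton (-0.36, 0.0029), monocyte (-0.84, 0.0029) and immediate early genes (-0.27, 0.00656). None remained with an estimated correlation, where the adjusted p was 0.265 to 0.505, nor with fry (0.198 to 0.553). S phase genes had a median of -0.02, opposite in sign to camera (adjusted p = 0.86). No member passed over all genes, and adjusted over the list alone 7 bile acid, 5 periportal, 4 pericentral and 1 hepatocyte identity gene of these lists did. Single libraries ended the call of fatty acid synthesis (0.0505 without Yap/Taz KO + CCl4 replicate 1), cytoskeleton (0.0751 without ctrl + CCl4 replicate 3), immediate early genes (0.122 without ctrl + CCl4 replicate 2, 0.295 without Yap/Taz KO + CCl4 replicate 1) and female-biased genes (0.413, 0.327 and 0.109 without ctrl + CCl4 replicate 2 and Yap/Taz KO + CCl4 replicates 1 and 2). The periportal score was 7.35 ± 0.29 in injured knockouts and 6.80 ± 0.16 in injured controls (two-sided exact permutation p = 0.1, the smallest possible with 3 against 3), and the G2 and mitosis score 5.73 ± 0.345 and 6.18 ± 0.201 (exact permutation p = 0.2).

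Some marker scores and genes had lower means beside the higher hepatocyte lists, and none of these genes passed. Which cells gave these transcripts, hepatocytes or others, was not tested. The cholangiocyte and progenitor score was 3.415 ± 0.342 log2 CPM in Yap/Taz KO + CCl4 and 3.89 ± 0.105 in ctrl + CCl4 (SD, n = 3), without overlap (difference -0.475, 95% interval -0.894 to -0.056; two-sided exact permutation p = 0.1), and its list did not pass (camera adjusted p = 0.108). Spp1 of that list lay between 46.8 and 169 CPM in the injured knockouts and between 291 and 416 in the injured controls (edgeR adjusted p = 0.556), and Lyz2 of macrophages averaged 583 ± 85.2 and 1145 ± 520.1 CPM (edgeR adjusted p = 0.983). The monocyte score was 4.15 ± 0.289 and 4.84 ± 0.378, and the lymphocyte score, from 2 tested genes, 1.63 ± 0.548 and 2.29 ± 0.337 (exact permutation p = 0.2 for both), each with overlap between the groups. The monocyte call was lost with an estimated correlation (adjusted p = 0.441). The macrophage (6.85 and 7.11), endothelial (5.90 and 5.80), stellate (5.90 and 5.87) and erythroid scores (4.285 and 4.08) overlapped too.

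**Figure D3:**
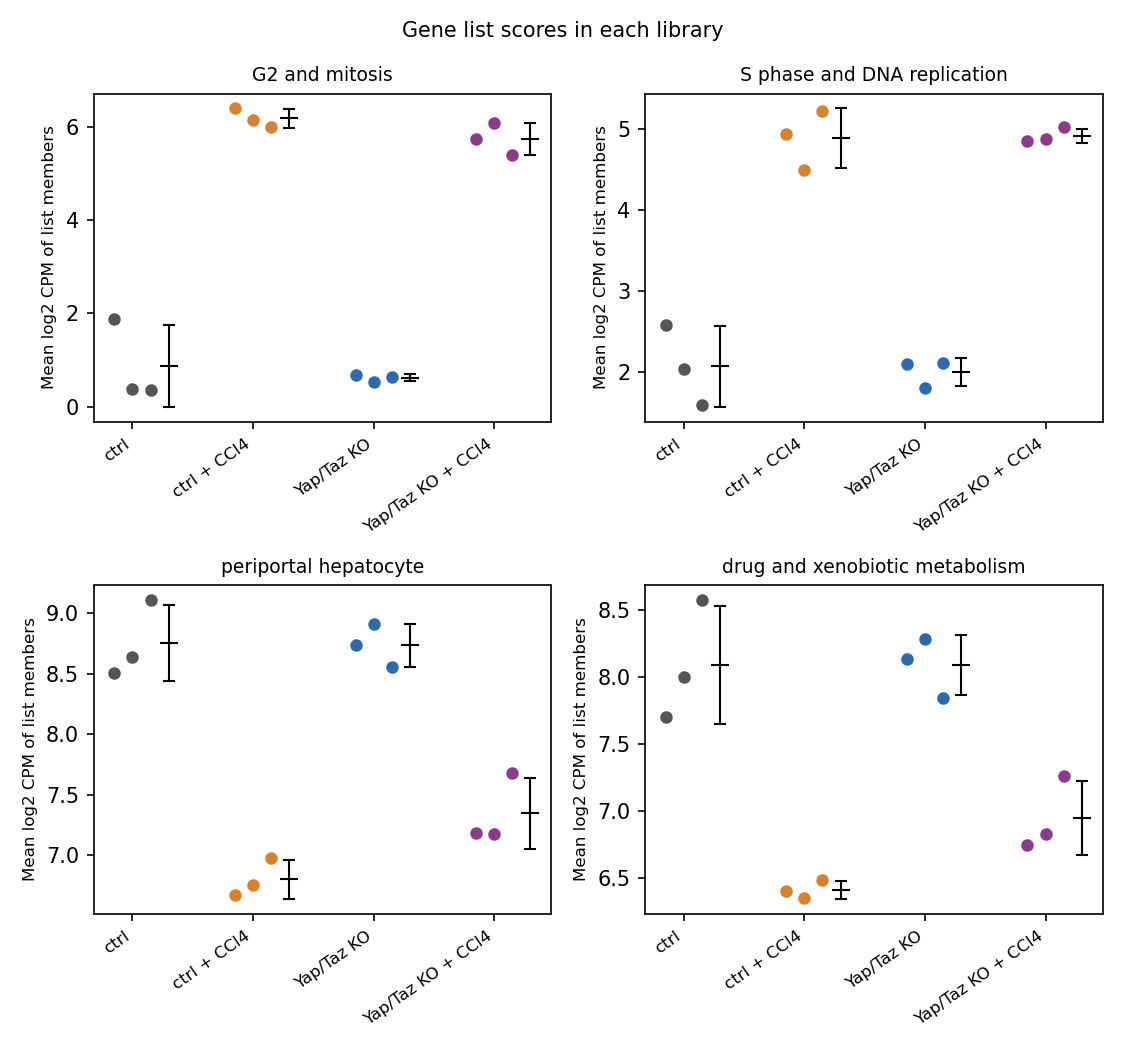
Mean log2 CPM of the members of 4 gene lists (y axes, not starting at 0) in each library of the 4 groups (x axes); points are libraries and the bar beside them is the mean with its SD (n = 3). The G2 and mitosis score was 5.73 in injured knockouts and 6.18 in injured controls, against 0.617 and 0.872 before injury.

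The knockout effects before and after injury correlated across genes with r = 0.085 and rho = 0.002 over 10780 genes, and 48.4% of genes had the same sign. As edgeR called 0 genes in either comparison, these values do not show whether the effects agreed or differed. Without Yap/Taz KO replicate 1 r was -0.037.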

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

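Tests with the marker score as covariate, the reading of the left-out libraries, and the test of Cyp2e1 were chosen after the results were seen, as were the limits of 75% and 25% of lists kept that count against and for an explanation and the bound below which the covariate decides nothing. Because the labels give only 1 vector arm, a knockout effect cannot be parted from an effect of the vector.

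The injury responses of both genotypes differed for 3 lists in the test of the difference itself: interferon response (camera adjusted p = 0.0111, median 0.59), periportal hepatocyte (0.0136, median 0.58) and drug metabolism (0.0136, median 0.52). With an estimated correlation the adjusted p was 0.938 for each. Periportal and drug metabolism were lost without ctrl replicate 3 (0.209 and 0.324), Yap/Taz KO replicate 3 (0.0549 and 0.0706) or Yap/Taz KO + CCl4 replicate 3 (0.0919 for both), and interferon without Yap/Taz KO replicate 2 (0.244) or Yap/Taz KO + CCl4 replicate 1 (0.0648). Of 100 splits drawn within injury states, 87 gave as many as these 3 lists (highest other 18), so chance is not excluded for lists; for genes the real count was 0, which all 100 splits match whatever the data (highest other 31), so that count decides nothing.

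In uninjured knockouts camera called interferon, macrophage, monocyte and erythroid lists lower and the 2 hepatocyte lists higher, but all 6 calls were lost with an estimated correlation (adjusted p = 0.841 for each) and with fry (0.588 to 0.783). A candidate explanation is the library ctrl replicate 1 alone: without it 0 lists were called and the median size of the 6 list medians went from 0.684 to 0.128. All 7 marker lists were highest in it among the 3 controls. The livers were perfused and the cells sorted, but how far this removed other cells is not given. Hbb-bs had 1408, 19 and 66 counts in the controls. The macrophage gene Cd5l averaged 312 ± 346 CPM in ctrl and 138 ± 99.8 in Yap/Taz KO. Of the genes in the 7 marker lists, 0 belong to another list. Without Yap/Taz KO replicate 2 the count was 0 too, but the medians of pericentral (0.231, against 0.219 with all libraries), monocyte (-1.83 against -2.29) and erythroid genes (-3.475 against -3.91) stayed close, while those of hepatocyte identity (0.068 against 0.157), interferon (-0.217 against -0.498) and macrophage genes (-0.575 against -0.87) were smaller. Cells of other types in the control libraries stay open: 3 of the 6 lists kept their call with the marker score as covariate (interferon, erythroid and macrophage, the last being part of that score and so not readable), but the score differed between the groups by -0.388 with a pooled SD of 0.951, too little to decide.

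In injured knockouts camera called 8 lists higher, 7 of them of hepatocyte metabolism or identity, and 4 lower, among them G2 and mitosis, but all 12 calls were lost with an estimated correlation (adjusted p = 0.265 to 0.505) and with fry (0.198 to 0.553). Against 1 library as the whole cause, at least 9 of the 12 lists kept their camera call at the preset correlation with any 1 injured library left out (fewest without Yap/Taz KO + CCl4 replicate 1). The 9 kept sit on the limit of 75%, which was set after the results were seen. A split mixing both genotypes among the injured samples also called 12 lists, so kept camera calls say little about a cause. Cells of other types stay open: all 12 lists kept their call with the marker score as covariate, but that score differed between the groups by only -0.045 (pooled SD 0.177), while the cholangiocyte and progenitor score, which it leaves out, was lower by -0.475 (95% interval -0.894 to -0.056) and the monocyte list was among the 4 lower. Whether the cholangiocyte and progenitor transcripts came from other cells or from hepatocytes was not tested. Less activation of CCl4 cannot be told apart, since Cyp2e1 before injury stood at -0.10 in knockouts with an interval of -0.95 to 0.74. The knockout and the vector both stay open.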

How the results depend on the processing

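The marker score as covariate and the 6-sample fits of single genes were added after the data were seen; the other settings were planned. Of the single genes, 1815 settings kept direction and side of the threshold, 27 newly passed it, 29 lost it and 30 turned sign. Only lists called in the main camera test were followed singly, so none could newly pass. For these, 872 settings kept the call and 114 lost it. The cause of the changes was not tested, except that a test against 1.5-fold asks for more and a left-out sample leaves fewer. Genes changed in control injury numbered 1320 with glmTreat and 1531 with the covariate; in knockout injury 969 and 643, and 1176 to 2331 with 1 sample left out. Without the low-count filter 210, 109 and 115 genes were called for uninjured knockout, injured knockout and interaction; with DESeq2 39, 18 and 11. For the injured knockout limma-voom with quality weights called 17, the 6-sample fit 5 (Yap1, Cyp2a5, and Plek, Notum and Il1rn, these 3 chosen after their values were seen) and the covariate 2 (Yap1, Cyp2a5). With 1 sample left out uninjured knockout gave 0 to 1 and injured knockout 0 to 3 genes. List counts with an estimated correlation were 5, 3, 0, 0 and 0 in the order control injury, knockout injury, uninjured knockout, injured knockout and interaction, and with fry 0 for the last 3; with the covariate uninjured knockout gave 3. With 1 sample left out uninjured knockout gave 0 to 15 lists and the interaction 1 to 9. The correlation of injury responses was 0.869 over called genes only and 0.691 to 0.777 with 1 sample left out, that of knockout effects -0.037 to 0.119; the latter over called genes gave no value, as 0 were called. DESeq2 gave no adjusted p for 2 pairs of gene and comparison.

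These single genes turned sign. In control injury Yap1 was 0.37 with library totals, 0.004 with RLE, 0.007 with DESeq2 and 0.045 with the covariate, and -0.24 to 0.15 with 1 sample left out; Wwtr1 was 0.16 with totals and -0.46 to 0.20; Ccn1 -0.69 to 0.47, Ccn2 -2.53 to 2.79 and Hbb-bs -3.49 to 0.035 with 1 sample left out. In knockout injury Yap1 was 0.27 with totals and -0.35 to 0.23 with 1 sample left out, Ankrd1 -1.20 to 0.073, and with the covariate Wwtr1 was -0.08 and Ccn2 -1.07. With 1 sample left out, Ccn2, Yap/Taz KO vs ctrl, was -3.745 to 1.77 and Mcm6 -2.13 to 0.30 for uninjured knockout, Amotl2 -0.36 to 0.14 for injured knockout, and in the interaction Yap1 was -0.32 to 0.25, Ccn1 -0.081 to 1.21, Ccn2 -1.18 to 4.34 and Amotl2 -0.11 to 0.41.

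The shared replicate numbers were not taken as pairs, since 7 of 18 same-number correlations, not all, were over 0.1 (-0.152 to 0.323) and the best match had the sample's own number in 15 of 36 tests. Between the uninjured groups the pairing correlations were 0.323, 0.244 and -0.026 for replicates 1, 2 and 3, so a structure shared by replicates 1 and 2 there is not ruled out. With the replicate block 2594, 2095, 0, 0 and 0 genes and 19, 19, 7, 13 and 3 lists were called in the order above. Depth of 1617761 to 3028951 counts limits low genes, and a 2-fold change was rarely recovered in simulated data.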

Other observations

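The genes named here were chosen after their values were seen, while the tests by splits of the samples were set out before their results were seen.

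Reg3b had 419 and 1040 counts in Yap/Taz KO + CCl4 replicates 1 and 2 and 1 in replicate 3, and at most 16 in any library of the other groups. Reg3a had 138, 514 and 0 counts in the same libraries. Acp1 had 140 and 177 counts in Yap/Taz KO + CCl4 replicates 2 and 3 and at most 10 in every other library. Xist had between 14 (ctrl + CCl4 replicate 2) and 395 counts, and Ddx3y 0 counts in every library. Notum, an inhibitor of Wnt signalling, had 59, 85 and 109 counts in Yap/Taz KO + CCl4 and 18, 19 and 24 in ctrl + CCl4, against 52, 40 and 28 in Yap/Taz KO and 59, 121 and 63 in ctrl.

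Splits of 3 against 3 number 10, too few for a share under 0.05, so only values are given. For genes in the control injury response the real split called 2427 and the highest other 0 (1 of 10 splits as large), and in the knockout injury response 1916 and 0 (1 of 10). For uninjured knockout against control the real split called 0 and 10 of 10 were as large, the highest other calling 46 (ctrl replicates 1 and 3 with Yap/Taz KO replicate 1) and another 43 (ctrl replicate 1 with Yap/Taz KO replicates 1 and 3). What gave these 46 and 43 calls was not tested, and the simulation of this comparison also called 27 of 10508 unchanged genes. Both of these splits put replicates 1 of the 2 groups against replicates 2, and with the replicate block the real split called 0 genes and 7 lists. For injured knockout against control all 10 splits called 0. For lists the real count and the highest other were 19 and 23 in controls (2 of 10 as large), 18 and 20 in knockouts (4 of 10), 6 and 15 before injury (8 of 10), and 12 and 12 after injury (2 of 10). Splits that mix injured and uninjured samples called many lists, so a count of lists alone sets no group apart.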
